A study of Mus musculus with 12 samples.

How the data were processed

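Gene expression was measured in mouse epiblast stem cells (EpiSCs) of genetic background 129. EpiSCs are pluripotent cells that resemble the epiblast of the embryo after implantation. Another label field calls the cells embryonic stem cells. Per the labels' protocols, total RNA was labelled with biotin and hybridised to Affymetrix arrays with 1 colour, 1 sample per array. The 12 arrays fell into 4 groups of 3, taken from the sample labels: untreated cells, cells given CHIR99021 (3 µM), cells given XAV939 (2 µM) and cells given both compounds. Replicate numbers came from the sample titles. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

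The values deposited by the authors were read as log2 expression per probe. The log2 base was inferred from their range, 2.52 to 14.3, because no header states the scale. Partek is named per the submitters' processing notes, with no version; the background correction, normalization and summary method were not given in the sources used here. Array medians lay between 5.22 and 5.27, so the deposited values were already on a common scale between arrays, but the distributions were not identical. No further normalization was applied before the tests. Arrays carry no read depth, and the number of arrays, 3 per group, limits the precision.

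The table held 35399 probes. Of these, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 11989 were not listed there, so they are unnamed here. Gene identifiers were looked up in the RefSeq gene table of assembly GRCm38.p6, used for names and for which genes overlap; 91 probes with 1 gene had no match and kept the annotation's symbol. The probe with the highest mean over all 12 arrays stood for each gene, which mattered for 999 genes with more than 1 probe and left 19938 genes. No coordinates were used, since the build behind the annotation is not given. Tbxt (also called brachyury), Tcf7 and several other list members were not analysed here, because no probe with 1 gene carried their name. No pair of arrays was identical, and correlations between arrays ranged from 0.990 to 0.995.

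Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 with statmod 1.5.0 (lmFit and eBayes, two-sided moderated test). Residual degrees of freedom were 8 and prior degrees of freedom 8.03. There were 6 contrasts: each treatment against untreated, both compounds against XAV939 alone, both against CHIR99021 alone, and the interaction, which is the CHIR99021 change with XAV939 minus that without it. Benjamini-Hochberg adjustment was made over genes within a contrast, and genes with an adjusted p under 0.05 were called. Standard errors (SE) are from the fit. Of 30 gene lists, 29 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a contrast; camera with an estimated correlation and fry were alternatives. Counts adjusted over the list alone are given beside counts over all genes. As a rough measure of background, the 95th percentile of the means of 1194 olfactory and vomeronasal receptor genes was 4.94.

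The design, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took, per contrast, up to 12 called genes higher and 12 lower by size of change, 11 fixed genes (Axin2, Lef1, Sp5, Nkd1, Cdx1, Tbxt, Nanog, Pou5f1, Sox2, Fgf5 and Klf2), up to 4 members with the smallest p of each list described, and, where no gene was called, the 3 genes with the smallest p. The alternatives were quantile normalization, median centring, filters on dim genes, other rules for probes, fits to the compared groups alone, eBayes with trend and robust settings, array weights, a replicate block, a fold threshold of 1.5 and leaving out each array. Chosen after seeing the data were cyclic loess normalization, quantile and cyclic loess normalization over the tested genes alone, the standard deviation of each array as a covariate, leaving out untreated replicate 3 and XAV939 replicate 2 together, brightness-matched random lists, and a ratio of mean effects. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

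The tests were tried on simulated data with the real means and variances of the 19938 genes and 200 changed genes per contrast. Noise was drawn independently for each gene. The shares recovered hold for that number of changed genes, since the adjustment is stricter where fewer genes change. For CHIR99021 against untreated, 74% of genes changed by 0.5 and 100% of those changed by 1 on the log2 scale were recovered, and 1.69% of calls were false. For XAV939 against untreated the shares recovered were 80% and 99%, with 5.79% false calls. For both compounds against untreated they were 80% and 98% (6.81% false), for both against XAV939 67% and 98% (6.25%), for both against CHIR99021 78% and 98% (2.22%), and for the interaction 37% and 94% (2.24%).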

Results

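The series asked which genes respond to CHIR99021, an inhibitor of GSK3 that stabilises beta-catenin, and to XAV939, an inhibitor of tankyrase that stabilises Axin and so lowers beta-catenin, in mouse EpiSCs. Cells were kept without serum for 12 h and then treated with CHIR99021 at 3 µM for 2 h, XAV939 at 2 µM, both compounds or neither, with 3 arrays per group. A serum content of 10% is also recorded for every sample, untreated ones included. The time with XAV939 is given as 2 h in the sample labels and as 4 h in the design text, and which is right is unknown. Values are log2 expression as deposited, with the log base inferred from their range. Changes are differences of group means on that scale.

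CHIR99021 alone raised the genes of the secreted factors Nodal and follistatin more than any other gene called. Nodal, a TGF-beta family ligand of the early embryo, rose from 6.82 ± 0.09 (SD, n = 3) in untreated cells to 8.58 ± 0.09, a change of 1.76 (SE 0.09). Fst, which encodes follistatin, an antagonist of activin, rose from 7.98 ± 0.10 to 9.79 ± 0.04, a change of 1.81 (SE 0.10). The Wnt/beta-catenin target Axin2 rose by 1.06 (SE 0.10), the homeobox gene Gbx2 by 1.14 (SE 0.09) and Sp5, another Wnt target, by 1.08 (SE 0.13), although the mean of Sp5 over all arrays, 4.66, lay below the background measure. Further higher genes were the kinase gene Sgk1 (0.77), the ephrin receptor gene Epha4 (0.77), the repressor gene Zeb2 (0.75), Zfp677 (0.74), and the microRNA genes Mir106a (1.02), Mir19b-2 (0.97) and Mir20b (0.87).

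The genes with the largest falls after CHIR99021 were Dido1 (-0.80, SE 0.08), Mab21l2 (-0.76), Ppp1r10 (-0.76), Gadd45b (-0.70), which responds to stress, Sema4c (-0.64) and Rhob (-0.57). Six4, Gm5154, Bmf, Gprc5c, Bahcc1 and Itgb8 fell by between 0.49 and 0.54. The pluripotency factor genes Pou5f1 and Sox2, at 11.5 and 11.2 on average, had changes of -0.02 and 0.01. Nanog had a change of 0.38 (SE 0.10) that did not pass (limma adjusted p = 0.123). Lef1, Nkd1, Cdx1, Fgf5 and Klf2 had changes between -0.14 and 0.17 and did not pass, with Cdx1 below the background measure at a mean of 4.54.

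By the limma test, 84 of 19938 genes were called with CHIR99021 against untreated, 51 higher and 33 lower. Among the 24 genes named by size, 13 kept their call in each of the alternative fits that tested them and 11 lost it in at least 1: Mir19b-2, Mir20b, Mab21l2, Sema4c, Rhob, Six4, Gm5154, Bmf, Gprc5c, Bahcc1 and Itgb8. The fold threshold of 1.5 was not among these fits. Single arrays moved the count by over 1.5 times: it was 44, 49 and 34 without untreated replicates 1, 2 and 3, and 35 and 45 without CHIR99021 replicates 2 and 3. It was 42 without untreated replicate 3 and XAV939 replicate 2 together, the 2 arrays with the lowest standard deviation of values. At a fold of at least 1.5 it was 30.

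Among the fixed lists, Wnt/beta-catenin target genes were shifted upward with CHIR99021. Of 23 measured members, 7 were called higher over all genes and none lower; adjusted over the list alone, 9 were higher and 2 lower (Myc and Ascl2). Axin2, Sp5, Znrf3 (0.62) and Tnfrsf19 (0.56) had the smallest p. The camera adjusted p was 0.000108, and 0.0376 with an estimated correlation. With fry the adjusted p was 0.000938. The other 7 lists called did not pass with an estimated correlation. With fry, 4 of them passed (adjusted p = 0.0246 for streak, 0.0362 for BMP, 0.0398 for aryl hydrocarbon receptor and 0.0399 for MYC genes) and 3 did not (0.0733 for ATF4, 0.0755 for Hippo/YAP and 0.155 for cholesterol genes).

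Of 21 primitive streak and mesendoderm genes, Wnt8a (0.72), Eomes (0.59) and Sp5 were called higher, and 5 members were higher and 1 lower adjusted over the list alone. The mean change was 0.13 but the median was -0.02, so this upward call (camera adjusted p = 0.0289; adjusted p = 0.263 with an estimated correlation) rested on part of the list. ATF4 and amino acid stress genes were called upward (camera adjusted p = 0.00732; adjusted p = 0.286 with an estimated correlation), with Ddit4 (0.52) and Atf3 (0.56) called among 20 and the same 2 adjusted over the list alone. Aryl hydrocarbon receptor targets were called upward with Tiparp (0.49) called among 9 and 3 higher adjusted over the list alone (camera adjusted p = 0.0225; adjusted p = 0.27 with an estimated correlation). MYC and ribosome biogenesis genes (20 measured) and cholesterol synthesis genes (16 measured) were also called upward with no member called over all genes (camera adjusted p = 0.0225 for each; adjusted p = 0.27 and 0.392 with an estimated correlation); adjusted over the list alone, none and 1 were higher. BMP targets (13 measured; camera adjusted p = 0.0328; adjusted p = 0.263 with an estimated correlation) and Hippo/YAP targets (14 measured; camera adjusted p = 0.0476; adjusted p = 0.286 with an estimated correlation) were called downward, also with no member called over all genes. Adjusted over the list alone, 1 BMP target was higher and 2 lower, and 1 Hippo/YAP target was higher and 5 lower. 

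Leaving out single arrays ended each of these 7 list calls in camera's test. The streak call ended without untreated replicates 1 or 2 or CHIR99021 replicate 3 (adjusted p = 0.0756, 0.0615 and 0.0688). The call of BMP targets ended without untreated replicates 1, 2 or 3 or CHIR99021 replicates 1 or 2 (adjusted p = 0.0502, 0.0538, 0.0704, 0.0701 and 0.153). That of Hippo/YAP targets ended without untreated replicates 1 or 2, CHIR99021 replicates 2 or 3, XAV939 replicate 1 or replicate 3 of both compounds (adjusted p = 0.197, 0.094, 0.163, 0.0566, 0.0522 and 0.0555). That of cholesterol synthesis ended without untreated replicate 1 or CHIR99021 replicate 3 (adjusted p = 0.3 and 0.0555), and that of ATF4 genes without untreated replicate 3 or CHIR99021 replicate 3 (adjusted p = 0.0704 and 0.0555). That of MYC and ribosome biogenesis genes ended without untreated replicate 3 (adjusted p = 0.0787), and that of aryl hydrocarbon receptor targets without untreated replicates 1 or 2 or CHIR99021 replicate 3 (adjusted p = 0.0502, 0.0542 and 0.0983).

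Other processing ended 4 of the 7 calls as well. A filter at the median expression, quantile normalization and cyclic loess ended those of BMP targets (camera adjusted p = 0.279, 0.0603 and 0.0745), cholesterol synthesis (camera adjusted p = 0.113, 0.0586 and 0.0745) and MYC genes (camera adjusted p = 0.13, 0.0819 and 0.0976). The filter also ended that of ATF4 genes (camera adjusted p = 0.0903). Without untreated replicate 3 and XAV939 replicate 2 together, the calls of BMP, ATF4 and MYC genes ended (camera adjusted p = 0.0686, 0.0686 and 0.071).

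**Figure D1:**
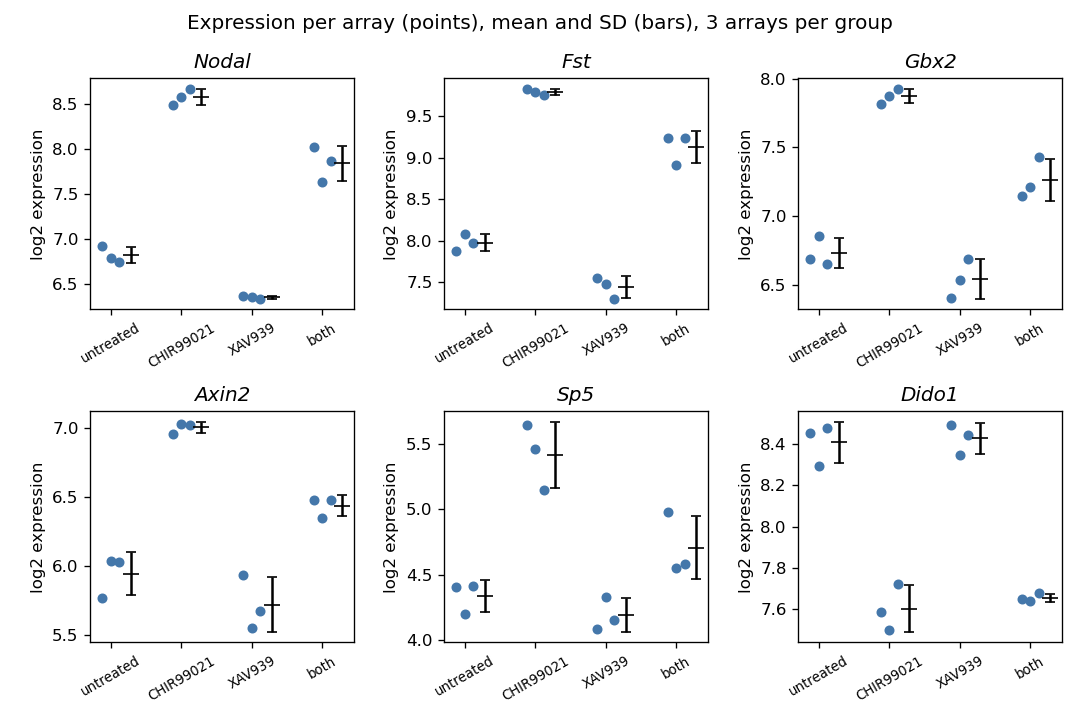
Log2 expression of 6 genes in each of the 12 arrays by treatment group, with points for arrays and bars for the mean and SD of 3 arrays; each vertical axis has its own range. Nodal averaged 8.58 with CHIR99021, 7.84 with both compounds, 6.82 untreated and 6.35 with XAV939 alone.

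XAV939 alone gave no called gene. The genes with the smallest p were Trim54 (-0.44, SE 0.07), the Notch ligand gene Dll1 (0.56, SE 0.10) and Nid1 (0.37, SE 0.07), none of which passed (limma adjusted p = 0.155 each). Nodal was at 6.35 ± 0.01 (SD, n = 3) against 6.82 ± 0.09 untreated, a change of -0.47 (SE 0.09) that did not pass over all genes (adjusted p = 0.155). The Wnt target Axin2 had a change of -0.22 (adjusted p = 0.418) and Sp5 of -0.15 (adjusted p = 0.681). Limma found 2241 genes (11.2%) at an unadjusted p under 0.05. Array weights gave 8 calls, 4 higher and 4 lower, the covariate for array standard deviation gave 3, and each of the other alternatives gave 0.

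Lists showed more than single genes with XAV939, though each list call rested on camera's preset correlation and none passed with fry (adjusted p = 0.0566 for streak, 0.0729 for ATF4 and 0.113 for Hippo/YAP genes). Primitive streak and mesendoderm genes were called downward as a list of 21, with a median change of -0.12 and no member called, over all genes or adjusted over the list alone (camera adjusted p = 0.00318; adjusted p = 0.195 with an estimated correlation). ATF4 and amino acid stress genes were called upward (camera adjusted p = 0.000754; adjusted p = 0.354 with an estimated correlation), with 6 of 20 members higher adjusted over the list alone and none over all genes; Atf3 had a change of 0.58 and Ddit4 of 0.47. Hippo/YAP targets were called upward, with 2 of 14 members higher adjusted over the list alone, Ccn1 and Amotl2 (camera adjusted p = 0.0428; adjusted p = 0.354 with an estimated correlation). This last call ended without untreated replicate 3, CHIR99021 replicate 2 or XAV939 replicates 2 or 3 (camera adjusted p = 0.229, 0.0522, 0.193 and 0.097). It also ended with the median filter, quantile normalization, cyclic loess and without untreated replicate 3 and XAV939 replicate 2 together (camera adjusted p = 0.157, 0.0748, 0.107 and 0.558). Wnt/beta-catenin targets were not called (camera adjusted p = 0.595).

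With both compounds against untreated, Fst (1.15, SE 0.10) and Nodal (1.02, SE 0.09) again had the largest rises. Bhlhe41, a transcriptional repressor of the circadian clock, rose by 0.90, Ddit4, a stress-induced inhibitor of mTORC1 signalling, by 0.67, and Znrf3, a Wnt target that lowers Frizzled levels, by 0.67. Atf3 (0.67), Ppp1r15a (0.61), Clcn7 (0.71), which encodes a lysosomal chloride transporter, Dpp7 (0.62), Dll1 (0.62), Fam13b (0.61) and Mir106a (0.74) were also higher. Mab21l2 (-0.93), Dido1 (-0.75), Tor4a (-0.63), Sox4 (-0.59), Nr1d1 (-0.52), Birc3 (-0.52) and Eya1 (-0.50) were lower. Axin2 rose by 0.49 (SE 0.10, limma adjusted p = 0.03), a call that ended without any 1 of the 6 arrays compared (adjusted p between 0.0159 and 0.109 over all alternatives), while Sp5 had 0.37 and did not pass. ATF4 and amino acid stress genes were the only list called by camera, upward (camera adjusted p = 0.000699; adjusted p = 0.502 with an estimated correlation), with 2 of 20 called higher over all genes and 7 adjusted over the list alone. The call ended with the median filter (camera adjusted p = 0.0853). By fry this list and, downward, BMP targets passed (adjusted p = 0.0308 each), where camera did not call BMP targets (camera adjusted p = 0.104). The upward camera calls of ATF4 genes with CHIR99021, XAV939 and both compounds all used the same untreated arrays. Camera did not call this list for both compounds against either compound alone. Atf3 averaged 8.30 untreated and 8.86, 8.88 and 8.97 with CHIR99021, XAV939 and both. Low values in the untreated arrays were not separated from a response to each compound.

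By limma, 225 genes were called with both compounds against untreated, 163 higher and 62 lower, and this count and its split moved with the processing. Quantile normalization gave 59 higher and 44 lower, median centring 324 higher and 58 lower, a filter at the median expression 446 higher and 82 lower, and one at the 25th percentile 251 higher and 101 lower. Array weights gave 382 higher and 168 lower, and the fit to the 2 groups alone 76 higher and 33 lower. At a fold of at least 1.5, 15 genes were higher and 4 lower. Of the alternatives chosen after seeing the data, cyclic loess gave 55 higher and 49 lower, and quantile normalization over the tested genes alone 47 higher and 59 lower. The count was 42 and 13 without untreated replicates 2 and 3, and 84, 10 and 82 without replicates 1, 2 and 3 of the arrays with both compounds. It was 12 without untreated replicate 3 and XAV939 replicate 2 together, and 20 with the standard deviation of each array as a covariate. Of the 225 genes, 8 kept their call in each alternative fit that tested them: Fst, Nodal, Bhlhe41, Ddit4, Znrf3, Fnip1, Zeb2 and, in the lower direction, Dido1. These fits do not include the fold threshold of 1.5. Of the 24 genes named by size, 18 lost their call in at least 1 of them.

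The deposited values varied in spread between arrays, and the change followed brightness. The standard deviation of an array's values averaged 2.16 ± 0.02 (SD, n = 3) untreated, 2.18 ± 0.01 with CHIR99021, 2.17 ± 0.03 with XAV939 and 2.20 ± 0.01 with both compounds. Untreated replicate 3 was lowest at 2.14, untreated replicate 1 and replicate 1 of both compounds were each at 2.18, and a difference between groups was not tested. With both compounds, the median change was -0.09 in the fourth decile of mean expression and 0.10 in the seventh.

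**Figure D2:**
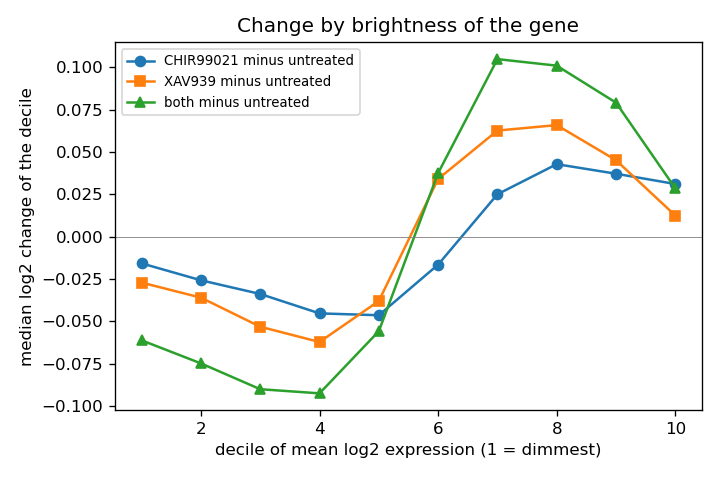
Median log2 change of genes in each decile of mean log2 expression (1 is the dimmest) for each treatment against untreated. With both compounds the median was -0.09 in decile 4 and 0.10 in decile 7.

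The response to CHIR99021 was also measured with XAV939 present, as both compounds against XAV939 alone. Fst (1.68, SE 0.10), Nodal (1.49, SE 0.09), Gbx2 (0.72), Axin2 (0.72), Wnt8a (0.66), Zeb2 (0.64), Epha4 (0.62) and Mir106a (0.68) rose. Mir367, a microRNA gene of a cluster active in pluripotent cells, rose by 0.96 (SE 0.14), Bhlhe41 by 0.81, Fnip1 by 0.60 and Nlrc4 by 0.61. Dido1 (-0.77), Gm14164 (-0.75), Ccn1 (-0.65), Thbs1 (-0.63), Zfp93 (-0.59), Sox4 (-0.59), Ppp1r10 (-0.58), Lrrn4 (-0.57), Pim1 (-0.56), Ccn2 (-0.56), Gprc5c (-0.55) and A930024E05Rik (-0.53) fell. Limma called 47 genes, 20 higher and 27 lower. At a fold of at least 1.5 it called 13 higher and 6 lower, and without XAV939 replicate 1 it called 13 higher and 8 lower, so which direction had more genes turned. The count was 21 and 26 without XAV939 replicates 1 and 2, 27 and 24 without replicates 2 and 3 of both compounds, and 21 without untreated replicate 3 and XAV939 replicate 2 together.

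With XAV939 present, Wnt/beta-catenin targets were called upward (camera adjusted p = 0.0256; adjusted p = 0.255 with an estimated correlation). Axin2 and Znrf3 (0.52) were called higher and Myc (-0.48, SE 0.09) lower among 23, and adjusted over the list alone 5 were higher and 2 lower. Hippo/YAP targets were called downward, with Ccn1, Ccn2 and Amotl2 (-0.46) called lower among 14, and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0191; adjusted p = 0.255 with an estimated correlation). Genes of the G2/M phase were called downward with a median change of -0.07 and no member called among 19, over all genes or adjusted over the list alone (camera adjusted p = 0.0191; adjusted p = 0.255 with an estimated correlation). The Wnt call ended without XAV939 replicates 1 or 3 or replicate 3 of both compounds (camera adjusted p = 0.0944, 0.168 and 0.124) and with the median filter (camera adjusted p = 0.315), the Hippo/YAP call without XAV939 replicate 3 or replicate 1 of both (camera adjusted p = 0.101 and 0.0936), and the G2/M call without XAV939 replicates 1 or 3 or replicate 2 of both (camera adjusted p = 0.0944, 0.101 and 0.0634). All 3 passed with fry (adjusted p = 0.0383 each). Fry also called streak genes (adjusted p = 0.0397) and Nodal/TGF-beta targets (adjusted p = 0.0383) upward, which camera did not (camera adjusted p = 0.0716 and 0.187). The Nodal/TGF-beta list holds Nodal itself, which rose by 1.49 in this comparison.

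The 84 genes called with CHIR99021 alone all changed in the same direction with XAV939 present, in a comparison that shares no array with the first. Of them, 23 were called in both: 15 higher, where independent lists would share 0.0512, and 8 lower, where they would share 0.0447. The median change in the direction of the first comparison was 0.50 without XAV939 and 0.34 with it, and 76 of the 84 changes were smaller. The slope through the origin was 0.69 (jackknife SE 0.04), and 0.64 over the 23 fixed Wnt/beta-catenin targets. The jackknife kept the 84 genes fixed, so its SE leaves out their selection. Genes chosen for their size regress toward smaller values: in simulated data with equal effects of 0.5 the slope was 0.92 where 1 was put in. When genes were chosen on 2 replicate numbers and measured in the left-out arrays, the mean slope was 0.74 and the ratio of mean effects, chosen after seeing the data, was 0.91 ± 0.05 (SD over 3 splits), so the size of the reduction was not settled.

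**Figure D3:**
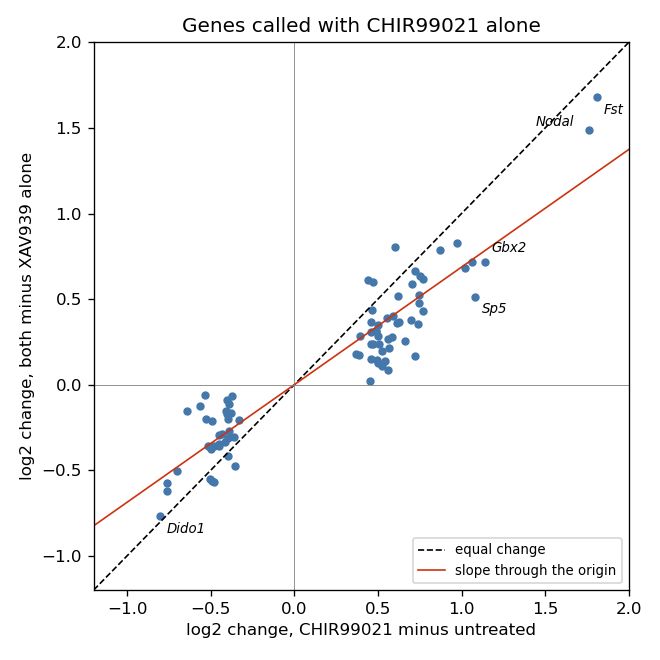
Log2 change with CHIR99021 alone (horizontal) against log2 change with both compounds relative to XAV939 alone (vertical) for the 84 genes called with CHIR99021 alone; the dashed line marks equal changes and the red line the slope of 0.69. All 84 points lie in the quadrants of shared direction.

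Both compounds against CHIR99021 alone tested what XAV939 did to CHIR99021-treated cells. Nodal (-0.74, SE 0.09), Fst (-0.66, SE 0.10), Gbx2 (-0.61, SE 0.09), Cited2 (-0.47, SE 0.08) and Cysltr1 (-0.45, SE 0.07) were the 5 genes called by limma, each lower. Axin2 (-0.57, adjusted p = 0.0788), Sp5 (-0.71, adjusted p = 0.0844) and Eomes (-0.49, adjusted p = 0.0788) did not pass. Single arrays turned this: Axin2 passed without XAV939 replicates 1 or 2, Sp5 without replicate 1 of both compounds and Eomes without replicate 3 of both (lowest adjusted p over all alternatives 0.0204, 0.0358 and 0.0181). Each of the 5 lost its call in at least 1 alternative fit. The count was 0 in the fit to these 2 groups alone and 0 without CHIR99021 replicates 2 or 3 or replicate 2 of both compounds. It was 1 without untreated replicates 1 or 2 or CHIR99021 replicate 1, and 3 without XAV939 replicate 3. It was 2 with median centring and with all probes tested separately, 1 with array weights and 3 at a fold of at least 1.5. Other settings raised it: it was 7 without XAV939 replicate 2, 8 with quantile normalization and 10 with the median filter. Of the alternatives chosen after seeing the data, cyclic loess gave 8, either method over the tested genes alone 9, and leaving out untreated replicate 3 and XAV939 replicate 2 together 1.

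In the same comparison 3 lists were called downward. Wnt/beta-catenin targets had 5 of 23 members lower adjusted over the list alone and none over all genes (camera adjusted p = 0.00254; adjusted p = 0.064 with an estimated correlation). Primitive streak and mesendoderm genes had 3 of 21 lower adjusted over the list alone, Eomes, Sp5 and Wnt5b (camera adjusted p = 0.000822; adjusted p = 0.064 with an estimated correlation). Posterior Hox and Cdx genes had none of 17 (camera adjusted p = 0.0495; adjusted p = 0.31 with an estimated correlation). Wnt pathway components were called upward with a median of 0.07 and none of 28 members passing over all genes or adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.31 with an estimated correlation). The call of Wnt components ended without CHIR99021 replicate 2 or replicate 3 of both compounds (camera adjusted p = 0.0548 and 0.1) and with the median filter, quantile normalization and cyclic loess (camera adjusted p = 0.259, 0.187 and 0.237). That of Hox and Cdx genes ended without untreated replicate 2, CHIR99021 replicates 1 or 3, XAV939 replicate 3 or replicates 1, 2 or 3 of both (camera adjusted p = 0.0556, 0.281, 0.0729, 0.0514, 0.0528, 0.0905 and 0.1), and with quantile normalization and cyclic loess (camera adjusted p = 0.187 and 0.244). With fry, Wnt targets and streak genes passed (adjusted p = 0.0111 each) and Wnt components and Hox and Cdx genes did not (adjusted p = 0.0775 and 0.101).

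The interaction, whether the CHIR99021 response differed with XAV939 present, had no called gene. Gm14164 (-1.09, SE 0.16, limma adjusted p = 0.107), Dnajb4 (-0.64) and Crygb, which lay below the background measure at a mean of 4.62, had the smallest p and did not pass, and Axin2 had -0.34 (SE 0.14) and Sp5 -0.57 (SE 0.18). Limma found 985 genes (4.94%) at an unadjusted p under 0.05, near the share that unchanged genes alone would give. The trend and robust settings, array weights and the fit without CHIR99021 replicate 3 each gave 1 call. No list was called (smallest camera adjusted p = 0.144).

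The CHIR99021 and XAV939 changes against untreated were correlated across genes (r = 0.40), but both use the untreated arrays. Simulated unchanged groups that shared 3 simulated untreated arrays, with independent noise for each gene, gave r = 0.50. Deviations of the real untreated arrays that many genes share are not in this simulation. The covariance was 0.00642 against 0.00453 simulated. The 3 untreated arrays do not split into 2 sides of at least 2 arrays, so part of the excess may come from sharing them, and genes are not independent replicates.

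Markers of other cells that the culture could hold were not called as lists by camera in any contrast. These tests compare groups, so they cannot show whether such cells were present equally in all groups. With CHIR99021 against untreated the camera adjusted p was 0.338 for fibroblast markers, 0.105 for trophoblast, 0.226 for extraembryonic endoderm, 0.136 for neural ectoderm, 0.639 for definitive endoderm and 0.746 for germ cells. Only 3 of the 10 genes of the 2-cell-like list were measured, so it was not tested. Fry called 1 of these lists, extraembryonic endoderm markers, downward with CHIR99021 (adjusted p = 0.0399, median change -0.04).

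The other 12 fixed lists were not called by camera in any contrast either, and fry called 1 of them, Nodal/TGF-beta targets, as given above. With CHIR99021 against untreated the camera adjusted p was 0.338 for naive, 0.715 for core and 0.746 for primed pluripotency genes, 0.726 for FGF/ERK feedback genes, 0.888 for immediate early genes, 0.944 for Nodal/TGF-beta targets and 0.633 for Notch genes. It was 0.746 for glycolysis and hypoxia genes, 0.75 for heat shock and unfolded protein genes, 0.24 for p53 targets, 0.944 for NRF2 targets and 0.941 for housekeeping genes. Single members still changed: Gbx2 among naive genes, Nodal among primed genes and Nodal/TGF-beta targets, Plk2 (0.50) among p53 targets, and Atf3 upward and Zfp36 (-0.37) downward among immediate early genes. Adjusted over the list alone, naive genes had 4 higher and 2 lower, primed genes 1 higher and 3 lower, immediate early genes 4 of each, and Nodal/TGF-beta targets 2 of each. The mean and median differed in sign for naive (0.08 and -0.04), primed (0.05 and -0.08) and Nodal/TGF-beta genes (0.09 and -0.04).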

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

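The test of the excess of higher genes was chosen after the result was seen; the splits of the arrays were planned. Signals outside the named genes were looked for among the 13610 probes with no symbol or several, which no comparison above uses. With limma, 2 of them passed for CHIR99021 against untreated and 1 for both compounds against untreated. Probe 10342868 was higher with CHIR99021 by 1.53 (SE 0.18, adjusted p = 0.0274) and probe 10599812 by 0.77 (SE 0.09, adjusted p = 0.0274). Probe 10342995 was higher with both compounds by 1.18 (SE 0.11, adjusted p = 0.00387), at a mean of 4.68. None is listed in the annotation used, and no explanation was tested.

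With both compounds against untreated 72.4% of calls were higher. After cyclic loess normalization, which removes trends with brightness, 52.9% were higher, so brightness-dependent scaling between arrays may account for the excess. A true change of many genes was not separated from scaling. The call counts under other splits of the same arrays follow: 3 arrays against 3 make 10 splits, too few for a share under 0.05. Only 1 split, the real one, reached 84 calls for CHIR99021 (highest other 1), 225 for both against untreated (highest other 0), 47 for both against XAV939 (highest other 1) and 5 for both against CHIR99021 (highest other 1). With a real count of 0 every split gives at least as many, so the 10 splits for XAV939 (highest other 1) and the 100 random splits of the 12 arrays for the interaction (highest other 12) decide nothing about chance. The 12 calls of 1 split point to a structure of the samples or to chance, and these were not separated.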

How the results depend on the processing

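None of the named genes reversed with a call in any alternative. Of 99 named calls, 38 held in each alternative, and of 677 named results without a call, 644 stayed so. The cause was not tested unless stated. The replicate numbers did not pair the arrays: same-numbered deviations correlated between -0.25 and 0.20, 6 of 18 pairs exceeded 0.1, and 4 of 12 arrays correlated best with their own number. With a replicate block the counts were 78, 0, 168, 43, 1 and 0 in the order CHIR99021, XAV939 and both against untreated, both against XAV939, both against CHIR99021, and interaction, where the main counts were 84, 0, 225, 47, 5 and 0.

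Leaving out single arrays gave, in that order, 34 to 97, 0 to 0, 10 to 284, 21 to 50, 0 to 7 and 0 to 1 calls. The slope of the CHIR99021 response ranged from 0.65 to 0.72 and the correlation of CHIR99021 and XAV939 changes from 0.32 to 0.52.

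For both compounds against untreated, quantile normalization gave 103 calls, median centring 382, filters at the median and the 25th percentile 528 and 352, the compared groups alone 109, array weights 550 and a fold of 1.5 19. Alternatives chosen after seeing the data gave 104 (cyclic loess), 106 and 107 (quantile and cyclic loess over the tested genes alone), 20 (array standard deviation) and 12 (without untreated 3 and XAV939 2). For CHIR99021, the fold of 1.5 gave 30 and leaving out these 2 arrays 42. For XAV939, array weights gave 8 and the array standard deviation 3. For both against XAV939, the fold of 1.5 gave 19 and leaving out these 2 arrays 21.

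For both against CHIR99021, quantile normalization and cyclic loess gave 8, the versions over the tested genes alone 9, median centring 2, the median filter 10, all probes separately 2, the compared groups alone 0, array weights 1, a fold of 1.5 3, and leaving out the 2 arrays 1. For the interaction, the trend and robust settings and array weights each gave 1. The slope, 0.69, was 0.64 on the fixed Wnt list, 0.74 with genes chosen on other arrays and 0.91 as a ratio of mean effects. The XAV939 slope was not given, since no gene was called. Nanog passed for CHIR99021 with the replicate block alone (adjusted p = 0.0341). Of 19 list calls, only Wnt targets with CHIR99021 held in each of 19 alternatives. Dim genes near background limit what fold changes can show.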

Other observations

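The lists described here were written after the data were seen, and all tests were chosen after the data were seen, the brightness test of the giant-protein genes before its own result was. Genes of the microRNA cluster of Mir106a and Mir363 were higher with CHIR99021: Mir106a (1.02), Mir20b (0.87), Mir19b-2 (0.97) and Mir92-2 (0.61) passed limma's test over all genes and Mir363 (0.61, adjusted p = 0.146) did not. The cluster's mean was 6.69 ± 0.18 (SD, n = 3) with CHIR99021 and 5.87 ± 0.27 untreated; it was picked for this pattern, so no test across arrays is given.

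Lysosome genes were higher with both compounds, with a median change of 0.18 over 43 members, 39 of them positive. Clcn7, Flcn, Fnip1 and Fnip2 were called, and are named after their values were seen. Without its called members the median, 0.16, lay above all random lists matched on brightness (percentile 100 of 10000), which fits a shift of the set as a hypothesis; matched lists treat genes as independent. Across arrays the whole list did not pass after adjustment over 10 such tests for CHIR99021 (exact permutation p = 0.0303, adjusted 0.0505) or XAV939 (exact permutation p = 0.0411, adjusted 0.0588). The 10 tests include those of the giant-protein genes and of both microRNA clusters described here, so the adjusted values depend on that choice.

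Genes of very large proteins, such as Mdn1 and Herc1, were higher in arrays with XAV939: the median of 59 members per array averaged 0.05 with XAV939 and 0.11 with both compounds, against -0.11 untreated and -0.05 with CHIR99021. Brightness-dependent scaling is argued against, since the median lay at percentile 100 of 10000 matched lists and, at 0.12, also after cyclic loess. Without members called with both compounds against untreated, the median, 0.14, lay at percentile 100 too. Matched lists treat genes as independent, and the choice of the list after its called members were seen favours a high percentile. For arrays with CHIR99021 against those without, the median, 0.07, lay at percentile 99.64, or 97.89 after cyclic loess. Without members called with both compounds against untreated, that median was 0.05, at percentile 94.57. Across arrays the whole list did not pass for CHIR99021 (exact permutation p = 0.258, adjusted 0.286). Whether a smaller shift also went with CHIR99021 was therefore not settled. Without called members, the 6 arrays with XAV939 still lay above the 6 without (exact permutation p = 0.00216 over 924 splits, adjusted 0.00541). The list was written after called members were noticed in these same arrays, so this p cannot decide whether XAV939 was the source. Differences in RNA quality or labelling batch cannot be told apart from XAV939 as the source of the 0.16 between these arrays, because no label gives either, so this may be technical.

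The 5 microRNA genes of the cluster of Mir302a and Mir367 had lower values with XAV939 (median -0.64) and higher ones with CHIR99021 (median 0.51), none called in either comparison, while Mir367 was called with both compounds against XAV939 alone, and this cluster too was picked for its pattern, so no test across arrays is given. The gene Larp7, which overlaps the cluster, had a change of 0.13 (SE 0.09) with XAV939, so its measured level did not fall. The probe that stands for Larp7 need not follow all of its transcripts, so they stay open as a source. A single array is argued against for the fall, since the lowest untreated array lay 0.29 above the highest with XAV939 alone, but not for the rise, where CHIR99021 replicate 2 lay only 0.0116 above the highest untreated array. General behaviour of microRNA probes is argued against for the rise, since the medians with CHIR99021 were -0.01 over all 292 other microRNA genes, -0.02 over the 98 above the background measure and 0.025 (SD 0.21) over the 10 with a mean of 7 or more, although Mir106a (1.02) and Mir363 (0.61) of the first cluster rose as much. For the fall it stays open: these sets had medians of -0.03, -0.06 and -0.21 with XAV939, and the lowest other gene, Mir18, had -0.42 against -0.58 to -0.69 in the cluster, so brighter probes may share part of it.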
